A study of Homo sapiens with 4 samples.

How the data were processed

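The data were 4 two-colour Agilent array files and 1 table of values of the whole series. Total RNA of 22RV1 cells transfected with SPINK1 siRNA or non-targeting siRNA was amplified and labelled with Cy3 or Cy5, per the labels' protocols. Signals were extracted with Agilent Feature Extraction, version 9.5.1.1 per the file headers and 9.1.3.1 per the submitters' processing notes. Spot intensity values (mean signal and median background of each channel) were used as deposited, before background correction. The deposited LogRatio, a log10 ratio of Cy5 over Cy3, and its p-value had been computed by Feature Extraction, per the file headers. The series' value table held the deposited log10 ratio with its sign turned on the dye flips (largest difference 5e-10) and was empty exactly where the LogRatio was 0, on 4 of 4 arrays. Its column medians were -0.0015, -0.0375, -0.0038 and 0.00032.

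Intensities were corrected with normexp (offset 50) and normalized within arrays by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Ratios were turned to SPINK1 siRNA over non-targeting siRNA as the labels give the dyes. Spots flagged as outliers were left out, and spots of one probe were averaged. Of 41000 probes, 23434 were named through their accession in the RefSeq gene table and 17566 kept the name in the files. Probes well above background on at least 3 of 4 arrays in at least 1 of the 2 RNAs were kept (25410), and each gene was represented by its brightest probe. This gave 19283 genes, of which 49 were dropped because outlier flags left a pair incomplete. Of 13 called genes with several probes, 5 had probes over 0.5 log2 units apart and 2 had probes of opposite sign. No 2 arrays shared nonzero LogRatio values.

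Same-numbered forward and dye-flipped arrays were averaged to 2 pairs, and an intercept was tested with lmFit and eBayes (two-sided, Benjamini-Hochberg, threshold 0.05), with 1 residual degree of freedom per gene and 5.22 in all after moderation. The offset reduces the apparent change of dim probes. Gene lists of at least 5 measured genes were tested with camera (preset correlation 0.01, and estimated). Named genes were SPINK1, up to 12 largest rises and 12 largest falls among called genes with a symbol and one sign on 4 arrays, and up to 4 called members of each list, or its 2 members with the smallest p where none was called, as values only. MBD2 was chosen after its values were seen. A result for 1 gene that the rule selects is not reported here. All 4 arrays came from 1 slide and 1 scan, so no slide or scan block was possible.

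The pipeline was tested on simulated data for this comparison, over 19234 genes with 200 changed. It recovered 82% of 1.5-fold changes, 98% of 2-fold and 100% of 3-fold and 4-fold changes, and called 22 unchanged genes. Those 22 were a larger share of all calls than the 0.05 threshold. The simulated genes varied independently, and more of them changed 3-fold or more than were called so in the real data. These shares are therefore not the power of the real fit, which did not call CANX at 1.86-fold (limma adjusted p = 0.0527). The alternatives were other background corrections, normalizations, filters, probe rules and replicate models, the series' value table, and leaving out each array.

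Control features, 1639 on each array, were left out. Genome position of probes is as the array annotation gives it, and the build is not given in the sources used here.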

Results

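Gene expression was compared between 22RV1 cells, a human prostate cancer cell line, transfected with siRNA against SPINK1 and the same line transfected with non-targeting siRNA. SPINK1 encodes a secreted inhibitor of trypsin-like serine proteases. RNA of both transfections was hybridised together on each of 4 two-colour Agilent arrays, 2 with the SPINK1 siRNA sample in Cy5 and 2 with the dyes exchanged. Each array file held 45015 features, of which 43376 were not controls. Between 61.2% and 64.6% of the non-control features were well above background in Cy3 and between 54.5% and 67.9% in Cy5. The lowest Cy5 value belonged to the second array with SPINK1 siRNA in Cy5, on which 9209 features had a log-ratio p-value below the 0.01 of the series' own filter, against 2317 to 3453 on the others. No spot of a called gene was saturated, and the number of arrays limits the precision. The labels do not say whether arrays numbered 1 and 2 came from separate transfections. The p-values therefore measure the spread between hybridisation pairs, which may be technical. Arrays were paired by number alone, and no other pairing was run. Disagreement between the 2 arrays of a pair is not part of that spread.

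The first question was whether the siRNA lowered its target. SPINK1 was 4.52-fold lower in the SPINK1 siRNA sample (log2 change -2.18, SE 0.083, n = 2 dye-balanced pairs, limma adjusted p = 0.0186), and lower on 4 of 4 arrays. The log2 ratios were -2.17 and -1.64 with the siRNA sample in Cy5 and -2.44 and -2.46 with it in Cy3. Its single probe, for NM_003122, lies on chromosome 5 between 147184404 and 147187778 in the array annotation, whose genome build the files do not state. The direction and size were close to the same whichever array was left out (log2 -2.04 to -2.31), but the limma call ended without either array carrying the siRNA sample in Cy3. Such a fit takes its spread only from the arrays of the other orientation. Its call therefore shows which arrays supplied the spread, not that the fall rests on the arrays left out. The call also ended with no filter on dim probes (adjusted p = 0.073) and with the 4 arrays fitted without pairing or a dye term (adjusted p = 0.148).

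The second question was which other transcripts changed. Of 19234 genes tested, 34 were higher and 2 were lower after SPINK1 siRNA, with changes among the higher genes of 1.59- to 2.91-fold. All 36 had one sign on all 4 arrays. The largest rise with a gene symbol was in LAMC1, the laminin gamma 1 chain of basement membranes (2.91-fold, log2 1.54, SE 0.11, adjusted p = 0.0362). PLAAT3, a phospholipase and acyltransferase listed on the array as HRASLS3, rose 2.87-fold, and MDK, the heparin-binding growth factor midkine, rose 2.81-fold. CDK6, a kinase of G1 progression, rose 2.68-fold on the probe used, and its second probe gave a change smaller by 1.13 log2 units. SLC25A22, a mitochondrial glutamate carrier, rose 2.47-fold, TMCO1, a membrane protein of the endoplasmic reticulum, 2.42-fold, and WIPI1, an autophagy protein that binds phosphoinositides, 2.31-fold. IQCN (KIAA1683 on the array) and MARVELD1 each rose 2.08-fold. HTRA1, a secreted serine protease, rose 1.93-fold, LMNB1, which encodes lamin B1, 1.90-fold, and RMI2, a subunit of the BLM helicase complex, 1.89-fold. Beside SPINK1, the only fall past the threshold was in PRSS23, which encodes a serine protease (1.67-fold lower, log2 -0.74, SE 0.065, adjusted p = 0.0481, lower on 4 of 4 arrays).

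**Figure D1:**
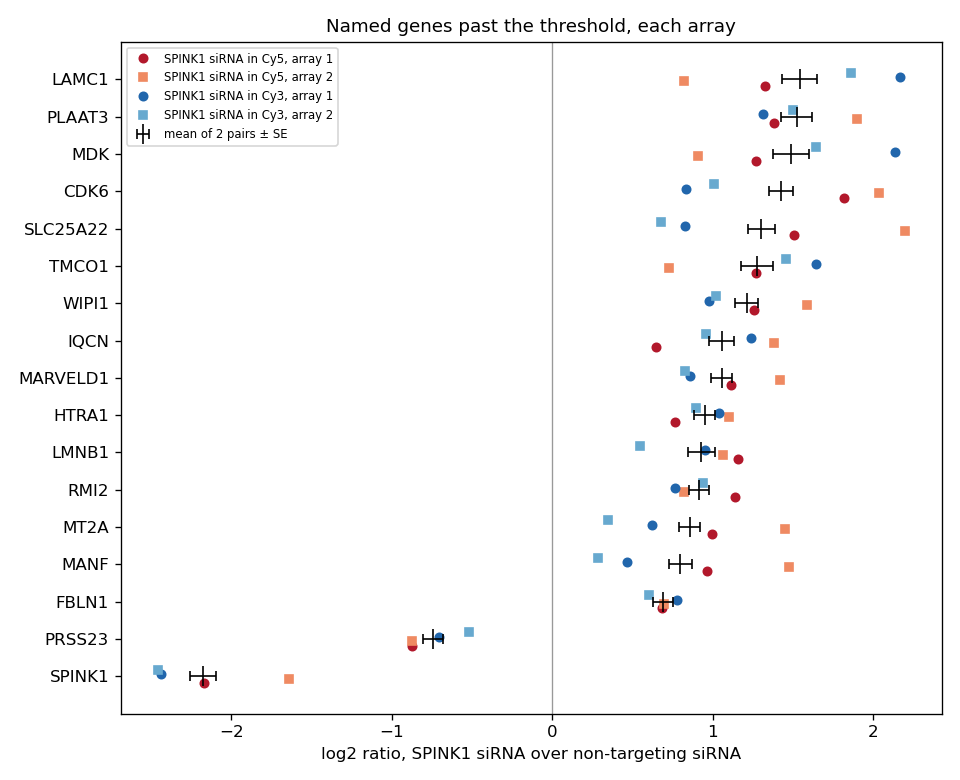
Log2 ratio of SPINK1 siRNA over non-targeting siRNA (x axis) for the named genes past the threshold (y axis); coloured points are the 4 arrays, and black marks are the mean of 2 pairs with the moderated standard error. SPINK1 and PRSS23 lie below 0 on all 4 arrays and the other genes above 0, with LAMC1 at a mean of 1.54 and SPINK1 at -2.18.

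The number of calls, and the balance of rises and falls, depended strongly on the processing. A smaller normexp offset of 16 gave 915 genes higher and 323 lower, and the deposited log ratios gave 1133 higher and 678 lower. Median centring, which moved the median of all genes to -0.13, gave 134 higher and 3743 lower, and all 36 called genes were still called in the same direction. Leaving out either array with the siRNA sample in Cy3 left 0 genes past the limma threshold in each direction, with 1617 and 2610 genes at an unadjusted p below 0.05. Leaving out the first or the second array with it in Cy5 gave 1856 higher and 1065 lower, and 670 higher and 367 lower. Each fit with an array left out takes its spread only from the arrays of the orientation left whole, so these counts turn on that orientation. In the main fit, 3536 genes had an unadjusted p below 0.05, 1969 of them higher.

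Gene lists fixed before the data were examined described which groups shifted against all other genes. Of 32 lists, 7 passed with camera's preset correlation, 3 higher and 4 lower. With an estimated correlation none passed (adjusted p = 0.802 for each of the 7 with an estimated correlation), so these shifts rest on the preset value.

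Genes of DNA replication and S-phase entry were higher as a list (38 measured, 33 above 0, camera adjusted p = 0.000172). None passed over all genes, and 5 were higher adjusted over the list alone, among them CCNE1, which encodes cyclin E1 (1.46-fold), and TK1, which encodes thymidine kinase (1.85-fold). The median of the list was above that of all genes on 3 of 4 arrays. The list that joins metallothioneins and heat shock genes was higher (27 measured, 17 above 0, camera adjusted p = 0.00703), and the shift lay in the metallothioneins. All 11 measured metallothioneins were above 0, with 1 higher over all genes, MT2A, a metal-binding protein gene (1.81-fold, adjusted p = 0.0362), and 9 higher adjusted over the list alone. Of the 16 heat shock genes 6 were above 0 and 10 below, with 1 lower adjusted over the list alone, and taken alone, a split chosen after the values were seen, they did not pass (adjusted p = 0.608). Metallothionein genes are near-identical in sequence, so their probes may not tell them apart and may count one change several times. Matrix proteases, their inhibitors and matrix receptors were higher as a list (25 measured, 19 above 0, adjusted p = 0.0118), with 1 member higher adjusted over the list alone, TIMP2, an inhibitor of matrix metalloproteinases (1.35-fold).

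Genes of amino acid synthesis and the ATF4 response were lower as a list (36 measured, 27 below 0, adjusted p = 0.00101). None passed over all genes and 6 were lower adjusted over the list alone, among them AARS1, an aminoacyl-tRNA synthetase (1.34-fold). Another was SESN2, a stress-induced regulator of nutrient signalling (1.29-fold), whose dye term passed its threshold (adjusted p = 0.0466). Only SESN2 of the 6 was lower on all 4 arrays. AARS1 had a log2 ratio of 0.24 on the second array with the siRNA sample in Cy3. Oxidative stress and glutathione genes were lower as a list (30 measured, 24 below 0, adjusted p = 0.00111), with 4 lower adjusted over the list alone, including the aldo-keto reductases AKR1C1 (1.45-fold) and AKR1C3 (1.36-fold), close paralogs whose probes may cross-hybridise. Respiratory chain subunits were lower as a list (51 measured, 32 below 0, adjusted p = 0.0168), with 0 members past the limma threshold over all genes or adjusted over the list alone. A list of protease inhibitors, most of them of serine proteases and SPINK1 left out, was lower (21 measured, 14 below 0, adjusted p = 0.0377), with 1 lower adjusted over the list alone, TFPI, the tissue factor pathway inhibitor (1.32-fold). It also held the 3 cystatins CSTB, CST3 and CST6, inhibitors of cysteine proteases that all lay below 0, and SERPINH1, a collagen chaperone; leaving these out, which was chosen after the values were seen, gave 17 measured, 11 below 0 and an adjusted p of 0.0235. The respiratory chain list did not pass in the deposited log ratios (adjusted p = 0.416), nor did the inhibitor list (adjusted p = 0.16). The respiratory chain list was lost as well with no background subtraction (adjusted p = 0.0732), with every probe tested (0.0523) and with the mean of probes (0.0612), and the inhibitor list with no filter on dim probes (0.145) and with every probe tested (0.0523). The respiratory chain list was also lost without the second array with the siRNA sample in Cy5 (adjusted p = 0.35) and without the first (0.0692) or second (0.111) with it in Cy3, and the inhibitor list without the second array in Cy3 (0.109). Median centring ended the calls of the replication list (adjusted p = 0.393), the matrix list (0.26) and the inhibitor list (0.287).

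**Figure D2:**
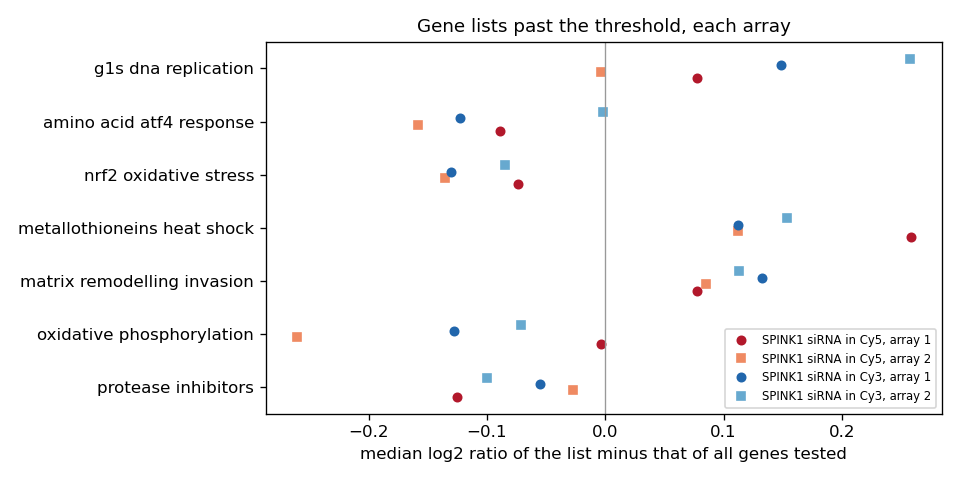
Median log2 ratio of each list that passed, minus the median of all genes tested (x axis), on each of the 4 arrays (points, coloured by dye orientation and number); lists are on the y axis. The oxidative stress list lies between -0.07 and -0.14 and the replication list between -0.004 and 0.26.

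Among serine proteases and their receptors 2 of 21 measured genes passed over all genes, HTRA1 higher and PRSS23 lower, and the list as a whole did not pass (adjusted p = 0.793). Over all genes, the unfolded protein response list held 1 higher gene, MANF, a secreted factor of the endoplasmic reticulum (1.74-fold, a call lost with no background subtraction, adjusted p = 0.0523). The autophagy list held 1, WIPI1. With every probe tested, CANX of the former list and LAMP1 and LAMP2 of the latter were called higher as well. LAMP2 passed on a probe at log2 0.97 (limma adjusted p = 0.0315), while the probe used for it was at 0.02. The unfolded protein response and autophagy lists did not pass (adjusted p = 0.126 and 0.815). Nor did the list of p53 targets and apoptosis genes (36 measured, adjusted p = 0.808). Each of these lists had members past the threshold in both directions when adjusted over the list alone. In the unfolded protein response list these included CANX (1.86-fold higher) and DDIT3 (1.35-fold lower). Such members therefore do not set the lists that passed apart from those that did not. Interferon and double-stranded RNA response genes, which transfected RNA can induce, did not pass (35 measured, adjusted p = 0.941). Both samples were transfected with siRNA, so a response common to them would cancel in the ratio. Androgen-induced genes did not pass either (32 measured, adjusted p = 0.544). Of markers of cells that a cell line culture should lack, FBLN1, a matrix glycoprotein of the fibroblast list, rose 1.61-fold on the probe used, while its second probe had the opposite sign and its call was lost with the mean of probes (adjusted p = 0.0923). The fibroblast list (adjusted p = 0.406), the leukocyte list (0.608) and the list for endothelium and red cells (0.733) did not pass.

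The series' own signatures required a deposited log-ratio p-value below 0.01 on all 4 arrays and one direction. Of 298 features that met the p-value requirement, 90 followed the siRNA, 205 were brighter in one dye on all 4 arrays, 167 of them in Cy5, and 3 had another pattern. The features that followed the siRNA gave 70 over-expressed and 12 under-expressed genes. The limma fit called 22 of the over-expressed genes higher and 2 of the under-expressed genes lower. That fit used the brightest probe of each gene, and with every probe tested the signature's own probes were called for 36 over-expressed and 5 under-expressed genes. Requiring p below 0.05 gave 176 over-expressed and 34 under-expressed genes, and leaving out the second array with the siRNA sample in Cy3 gave 133 and 44.

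The under-expressed signature also held, chosen after its values were seen, a probe for NM_015832, a short transcript of MBD2, a reader of methylated DNA. In the deposited ratios it was lower on 4 of 4 arrays, as the signature requires. The probe was well above background in the non-targeting sample on 4 of 4 arrays and in the SPINK1 siRNA sample on 1 of 4, so the size of its change is not read from those ratios. With the normexp offset, which shrinks dim probes, it was also lower (adjusted p = 0.0403 with every probe tested). The other MBD2 probe, for NM_003927, had a log2 change of -0.07 (SE 0.068, adjusted p = 0.657).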

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

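The tests of the MBD2 probe were chosen only after the result was seen. Among 68 named genes, 2 had 1 array far from the others, and chance gives about 1 in 20. CCNE1 had a log2 ratio of 0.76 on the first array with the siRNA sample in Cy3 against 0.45 to 0.48 on the others. IRF7 had 0.17 on the second array with it in Cy5 against -0.51 to -0.63 on the others. Of 17 named genes past the threshold, 3 differed between the dye orientations by the dye term of the limma fit. Their mean log2 ratio with the siRNA sample in Cy5 minus that in Cy3 was -0.94 in LAMC1 (adjusted p = 0.046), 1.00 in CDK6 (adjusted p = 0.0228) and 1.1 in SLC25A22 (adjusted p = 0.0445).

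More genes were called higher than lower. For genes brighter than the median gene, a fall hidden by the detection floor was argued against, since 31 of the 33 called there were higher (93.9%). These were most of the 36 calls, so the share says nothing about falls of dimmer genes, whose changes the offset shrinks. For dimmer genes the explanation stayed open. Differences between hybridisations stayed open: the contrast of arrays numbered 1 with arrays numbered 2 called 0 genes in limma (634 at an unadjusted p below 0.05). The bound set for that test was wrong for this design, because same-numbered arrays shared no deviation (correlation -0.05) and a fault of 1 array adds spread to the contrast, not calls. Centring of the log ratios met the bound set beforehand for it as the cause of the balance of calls. It was kept open by a condition added after the values were seen. Under median centring 3.46 percent of the called genes were higher, but that scaling moved the median of all genes to -0.13, which pushes genes below 0 together. All 36 called genes were still called in the same direction. The deposited log ratios had no such shift (median -0.0032), and 62.6 percent of their called genes were higher, which also met the bound.

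Dye bias of the lists' genes was argued against for 6 of the 7 lists that passed, which had a median on one side of all genes on all 4 arrays. The replication list did not, so for it dye bias stayed open. All 7 were selected for a shift over these same arrays, which makes a median on one side more likely. Leaving out an array left at least 5 of the lists called in the same direction, the bound set against one array as the cause. That cause was argued against only for the lists that stayed called each time. These were the replication, metallothionein and heat shock, matrix, amino acid and oxidative stress lists. For the respiratory chain and inhibitor lists, which were lost in some of these fits, one array as the cause stayed open. Correlation between genes stayed open. No list passed with an estimated correlation, but with 1 residual degree of freedom per gene that test could hardly pass any list.

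The probe for the short MBD2 transcript fell while the other MBD2 probe did not pass. It was lower on 4 of 4 arrays, but its choice from the signature required that, so one faulty array stayed open. SPINK1 RNA bound by the MBD2 probe was tested by its log2 ratio minus that of SPINK1, which averaged -0.375 (SE 0.182). This passed the bound set for the test, 2 standard errors, by a narrow margin (-2.06), with the probe below SPINK1 on 3 of 4 arrays. That standard error was taken over the 4 arrays without regard to the dye orientation. Because the probe lay near background in the siRNA sample, these sizes exclude nothing and the explanation stayed open, and an off-target effect of the siRNA was not tested.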

How the results depend on the processing

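The estimated correlation in the fit without pairs, and the lists limited to some members, were chosen after the data were seen. SPINK1 kept its direction under all alternatives run, and its call ended with no filter on dim probes (log2 -2.18, adjusted p = 0.073), without pairing or a dye term (-2.18, adjusted p = 0.148) and without either array with the siRNA sample in Cy3; its range when an array was left out was -2.31 to -2.04. With 1 of the 4 arrays left out, the spread came only from the arrays of the orientation left whole, so those calls turn on that orientation. Of 16 other named called genes, none of 176 alternative values turned direction, 142 stayed past the threshold and 34 did not (Aquantile and the series' value table not counted, since they repeat other values); of 64 values with an array left out, 32 stayed past it. None of these 16 genes stayed past the threshold with no filter on dim probes, or without pairing or a dye term. All 16 had one sign on all 4 arrays in the main fit, so a turned direction was unlikely. Genes higher and lower were 915 and 323 with offset 16, 1133 and 678 with deposited log ratios, and 1132 and 678 with the series' value table. They were 134 and 3743 with median centring, 103 and 13 with both channels above background on all arrays, and 64 and 8 with every probe tested. With an intensity trend they were 1020 and 350, and with no filter 0 and 0 (4632 at an unadjusted p below 0.05). Leaving out an array gave 0 to 1856 higher and 0 to 1065 lower, the lone array of an orientation being assumed to vary like the others. Aquantile leaves ratios untouched, so its equal counts test nothing.

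Same-numbered arrays share only a number: their deviations correlated at -0.05 over genes. No replicate block gave 117 higher and 14 lower with a dye term, and 0 and 0 without pairing or dye term (1679 at an unadjusted p below 0.05). With estimated correlation 0 lists passed, in the pairs and with no block, where few residual degrees of freedom made a pass nearly impossible. A slide or scan block was not run, since there was 1 of each. The signatures held 23 and 4 genes at p below 0.001, 176 and 34 at 0.05, and 191 and 71 on at least 3 of 4 arrays. Leaving out an array gave 80 to 133 over-expressed and 20 to 44 under-expressed genes. Median centring turned the signs of HOXB13 (-0.0045), SREBF2 (-0.033), LCP1 (-0.050) and CD79A (-0.067), none past the threshold. Heat shock genes without the metallothioneins had the opposite direction to their joint list (adjusted p = 0.608). Except where an alternative removes arrays or genes, the cause was not tested. Signal near background limits dim probes.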

Other observations

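The other lists fixed before the data were examined did not pass with camera's preset correlation, and their members are given as values. Mitosis genes had 28 of 42 measured members above 0 (adjusted p = 0.119), with PLK1, a mitotic kinase, at 1.77-fold and 3 members higher and 1 lower adjusted over the list alone. Wnt and Notch targets had 19 of 24 above 0 (adjusted p = 0.0935), with HES1 at 1.36-fold, mainly with the siRNA sample in Cy5 (log2 0.92 and 0.88 against 0.02 and -0.06 in Cy3, dye-term adjusted p = 0.0203), and 4 members higher and 1 lower adjusted over the list alone. The EGFR and MAPK response list had 23 of 32 above 0 (adjusted p = 0.133), with EGR1 at 1.37-fold. Its member AREG, which encodes an EGFR ligand, was at 1.36-fold lower and past the threshold for the dye term (adjusted p = 0.0384). Ribosomal proteins had 34 of 48 below 0 (adjusted p = 0.126), and their median against all genes ranged from -0.27 to 0.24 over the arrays. Reference genes had 16 of 26 below 0 (adjusted p = 0.146).

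Adjusted p was 0.257 for TGF-beta and BMP targets, 0.36 for neuroendocrine markers, 0.548 for NF-kB targets and 0.608 for both cholesterol synthesis and mesenchymal genes. It was 0.635 for RNA interference machinery, 0.648 for hypoxia and glycolysis, 0.686 for STAT3 targets and for epithelial junction genes, 0.808 for prostate luminal and basal markers and 0.835 for fatty acid synthesis. In the RNA interference list DICER1 was at 1.36-fold lower and MOV10 at 1.35-fold higher, and its median (log2 -0.0045) and mean (0.06) differed in sign. Median and mean also differed in sign for fatty acid synthesis (0.038 and -0.0021) and for markers of endothelium and red cells (-0.015 and 0.036).

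Log ratios turned to one direction correlated over genes, which are not independent replicates, at 0.67 between the arrays with the siRNA sample in Cy5 and at 0.63 between those with it in Cy3. Across orientations the correlations were between -0.37 and -0.13. Before the ratios were turned these were between 0.13 and 0.37, so over all genes the orientations shared more by dye than by siRNA. The values within an orientation therefore do not measure the siRNA response alone. The dye term passed its threshold for 1896 genes, 1105 of them brighter in Cy5. The direction of the ratios was taken from the labels, and SPINK1 was lower on all 4 arrays.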
